A study of Pyrus pyrifolia with 5 samples.

How the data were processed

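Flesh RNA of Japanese pear fruit (Pyrus pyrifolia, cultivar 'Housui') was hybridised to 14 single-colour Cy3 oligonucleotide arrays, with 3 arrays at 105 days after full bloom, 2 at 119 days, and 3 each at 133, 140 and 147 days. The labels merge the arrays of each time point into 1 sample record, and the design text states that each experiment at a time point used different trees. The arrays were therefore taken as the replicates. Total RNA was amplified linearly and labelled with a single dye, per the labels' protocols.

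The spot intensity of each array was extracted by the authors with Agilent Feature Extraction 9.5.1.1 under protocol GE1-v5_95_Feb07, per the file headers. That software subtracted the local background and a spatial trend and removed a multiplicative trend within each array, so the deposited processed intensity is not scaled between arrays. The deposited values merged by time point hold a relative signal, merged to a single column for each time point. Its normalization is not given in the sources used here. Set against the arrays, each of its columns was the geometric mean of the processed intensities of that time point's arrays divided by 1 constant, within 0.01 on the log2 scale for 86.55% to 92.98% of probes, with a floor of 0.01. The medians of the authors' columns were 0.379, 0.378, 0.260, 0.283 and 0.274 in time order. What the constants were taken from stays unknown, so those merged values were used only as an alternative.

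Each array holds 39161 features, of which 37744 are probe spots and 1417 are controls. The probe spots carry 18872 probes of 60 bases, 2 spots each, made for 9812 cloned cDNAs. For 9060 clones the array has an F and an R probe at different places of the clone, and for 752 clones it has 1 probe. The description of every probe is Unknown in the files and none is placed on a chromosome. No table that pairs probes with genes was used here, so probes are given by their IDs, with the sequence for all named probes except NFR6_02_03mF and NLE1_11_06mR. The 30 gene lists fixed beforehand by words of the gene descriptions, with their set tests, could not be run for this reason.

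Values were log2 of the processed intensity minus the 75th percentile of that array over its probe spots. Spots flagged as outliers were left out, control spots were left out, and the 2 spots of a probe were averaged. A value of -2 thus lies 2 log2 units below the array's 75th percentile. A floor of 1 was set for the processed intensity, and 0 spots lay below it. A probe was tested if it was well above background on every array of at least 1 time point, which kept 14158 probes from 8065 clones. Between 65.41% and 75.82% of all probes were well above background on an array. The number of arrays limits the precision.

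The values were fitted with limma 3.58.1 in R 4.3.3, with figures drawn with matplotlib 3.10.9 in Python 3.11.15. All 14 arrays entered 1 linear model with a mean per time point, and eBayes moderated the variances (9 residual degrees of freedom and 2.40 prior degrees of freedom). A moderated F-test asked which probes differed between any of the 5 time points, and 5 two-sided contrasts compared each time point with the next and 147 days with 105 days. P-values were adjusted by Benjamini-Hochberg over the probes tested, separately for each contrast, at a threshold of 0.05. Counts of probes that changed at least 2-fold apply that fold to the estimate on top of the adjusted p.

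Where a probe was not well above background on any array of 1 time point, the fold is given as a lower bound. The bound sets the mean of the brighter time point against a floor. For each array of the dimmer time point, that floor is the higher of the lowest signal among probes well above background and the probe's own signal. The rule for the probes named in the text was fixed before the data were examined. Since no probe has a gene name, the rule takes the 2 largest rises and the 2 largest falls of each comparison among probes past the threshold. Each of them also had to be well above background on all arrays of at least 1 of the 2 times and to change the same way in every pair of arrays.

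The fit was tested on simulated data for the 105 to 147 day contrast over 14157 probes, with 100 probes changed 1.5-fold and 100 changed 2-fold. The contrast recovered 69% of the 2-fold and 39% of the 1.5-fold changes, and 7 of its 115 calls were false. The median simulated 2-fold change was estimated at 1.00 on the log2 scale. The simulated noise was drawn separately for each probe and array, and only 147 days was changed. These shares need not hold where probes or arrays of a slide share deviations.

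Arrays lay on 7 slides, and each slide held a single time point. The arrays of 133 and of 147 days were each spread over 2 slides, so slide was entered as a random block in an alternative fit. The arrays were scanned in 2 sessions. The 105, 133 and 140 day arrays were scanned in session 1, and the 119 and 147 day arrays in session 2. A term for session cannot be separated from the time points, so contrasts within a session (105 to 140 days and 119 to 147 days) are given beside those that cross sessions.

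The alternatives fixed before the data were examined were quantile normalization, median centring, normexp background correction with an offset of 50, other filters on dim probes, and outlier spots kept. They also included fits of only the 2 time points compared, eBayes with trend and robust settings, array weights, replicate number as a block, slide as a random block, each array left out in turn, a 2-fold threshold, a linear trend in days and the deposited table of merged values. Scaling on 7 spike-in probes, a block for arrays with high spike-in signal, a trend with scan session and the within-session contrasts were chosen after seeing the data. That block holds both 119-day arrays and array 3 of 147 days. Its size is therefore set only by array 3 against arrays 1 and 2 of 147 days. No 2 arrays held identical values.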

Results

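Gene expression was measured in the flesh of ripening 'Housui' Japanese pear at 105, 119, 133, 140 and 147 days after full bloom, and the labels state that fruit was best for eating at the last of these times. Each time point had 3 arrays, except 119 days, which had 2, and each array stands for different trees. The median processed signal of an array lay between 426.5 and 610.6, and its 75th percentile between 3623 and 5373. The share of probes well above background was 73.95% ± 1.71 (SD, n = 3 arrays) at 105 days and 73.91% ± 1.65 (SD, n = 2) at 119 days. It was 67.6% ± 1.93 (SD, n = 3) at 133 days, 69.0% ± 0.873 (SD, n = 3) at 140 days and 68.53% ± 1.52 (SD, n = 3) at 147 days. The median SD of a probe between arrays of 1 time point was 0.168 on the log2 scale, against 0.0729 between the 2 spots of a probe on an array. By time point this SD lay between 0.113 and 0.120 from 105 to 140 days and was 0.204 at 147 days.

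The first question was which transcripts differed between any of the 5 times. Of 14158 probes tested, 11981 (84.62%) differed by the moderated F-test at the adjusted threshold of 0.05, and 5229 (36.93%) of the tested probes also had a range of at least 2-fold between their highest and lowest time. The highest mean fell at 105 days for 3219 of them (26.87%), at 119 days for 2859 (23.86%), at 133 days for 1290 (10.77%), at 140 days for 1738 (14.51%) and at 147 days for 2875 (24.0%). The lowest mean fell at 105 days for 3563 and at 147 days for 3699. A total of 826 probes had a higher mean at each successive time and 1204 a lower one. Among the probes that differed, 520 stood at least 2-fold higher at 119 days than at both 105 and 133 days, and 507 of these had their highest mean of all 5 times at 119 days. Array 3 of 147 days stood above arrays 1 and 2 for 86.4% of these 507 probes, against 53% of all probes. Among the probes with a range of at least 2-fold, the highest mean fell at 105 days for 36.53%, at 119 days for 28.72%, at 133 days for 4.72%, at 140 days for 7.80% and at 147 days for 22.22%. The times of the highest mean depend on the processing: 2522 probes were highest at 133 days with median centring and 2142 with no filter on dim probes, and 900 were highest at 140 days with slide as a random block. With spike-in scaling 169 were highest at 119 days, 190 at 133 days, 5894 at 140 days and 1624 at 147 days.

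Arrays of 1 time point correlated across probes with a mean r between 0.988 and 0.995. The correlation with the 105-day arrays fell from 0.973 at 119 days to 0.962 at 133 days, 0.935 at 140 days and 0.904 at 147 days; probes are not independent replicates. The first principal component carried 66.76% of the variance and placed the arrays of 105 days between -88.13 and -77.57 and arrays 1 and 2 of 147 days at 88.88 and 88.33. Array 3 of 147 days lay at 57.94, close to array 2 of 140 days at 59.01. On the third component (8.91%) it lay at 35.96, near the 119-day arrays at 41.45 and 38.08, while arrays 1 and 2 of 147 days lay at 10.62 and 9.28. The spike-in signal above the 75th percentile was 1.90 on this array and 2.06 and 2.18 on the 119-day arrays, against 0.24 to 1.28 on the other 11.

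**Figure D1:**
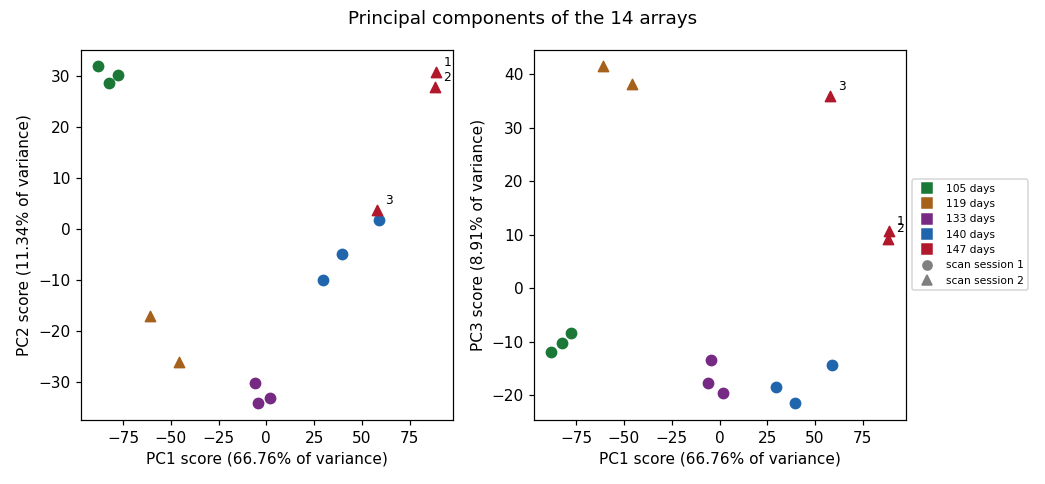
Scores of the 14 arrays on principal components 1 and 2 (left) and 1 and 3 (right), in arbitrary units, with 1 point per array, colour for days after full bloom, shape for scan session and numbers on the 147-day arrays. The first component runs from the 105-day arrays (lowest -88.13) to the 147-day arrays (highest 88.88), and array 3 of 147 days lies apart from arrays 1 and 2 on all 3 components.

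The comparison of fruit at eating maturity with fruit at the first sampling, 105 to 147 days, showed the widest change. In total 4383 probes rose and 4701 fell, together 64.16% of the probes tested. At least 2-fold changes were seen for 1239 rising and 2167 falling probes, and at least 4-fold changes for 315 rising and 1022 falling probes. The probe NFR6_13_05mR (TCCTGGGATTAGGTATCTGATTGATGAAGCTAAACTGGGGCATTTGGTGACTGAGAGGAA) was not well above background on any array of 105 days and reached 3.80 ± 1.15 (SD, n = 3) at 147 days, a rise of at least 2586-fold (adjusted p = 2.32e-07). Its log2 mean passed through -4.32 at 133 days and 0.03 at 140 days. The F probe of the same clone, also not well above background on any array of 105 days, rose at least 5.98-fold (adjusted p = 0.000179; 4.17 to 9.94-fold with 1 array left out). The probe NFR6_29_50mF (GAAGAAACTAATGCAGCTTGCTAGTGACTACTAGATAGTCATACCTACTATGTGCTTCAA) rose at least 2020-fold, from not well above background on any array of 105 days to 3.44 ± 1.04 (SD, n = 3) at 147 days (adjusted p = 2.73e-07). The R probe of its clone rose at least 1296-fold (adjusted p = 5.38e-07). With 1 array left out the bounds were 1983 to 4084-fold for NFR6_13_05mR, 1570 to 3057-fold for NFR6_29_50mF and 1011 to 1967-fold for that R probe.

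The widest falls over the same interval were of probes brighter than the array's 75th percentile at 105 days. The probe NFW1_06_30mR (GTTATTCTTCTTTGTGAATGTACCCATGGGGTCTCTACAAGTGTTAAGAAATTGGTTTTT) stood at 1.43 ± 0.54 (SD, n = 3) at 105 days and was not well above background on any array of 147 days, a difference of at least 336.2-fold (adjusted p = 1.92e-08). The F probe of that clone was at least 27.29-fold lower at 147 days (adjusted p = 1.26e-07). The probe NFR2_27_38mS (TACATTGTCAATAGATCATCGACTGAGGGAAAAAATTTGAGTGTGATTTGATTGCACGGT), the single probe of its clone, stood at 0.68 ± 1.03 (SD, n = 3) at 105 days and was at least 200.5-fold lower at 147 days (adjusted p = 6.92e-07). Over the alternatives the log2 change of NFW1_06_30mR ranged from -10.31 to -7.04 and that of NFR2_27_38mS from -9.36 to -6.20. The smallest change of each lies, as a fold, below the bound given. A set of 661 probes was well above background on all arrays of 105 days and on none of 147 days, and 57 probes showed the reverse. The level to be exceeded differed between these times, since the median spot background of an array was 33 to 34 at 105 days and 46 to 49 at 147 days.

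**Figure D2:**
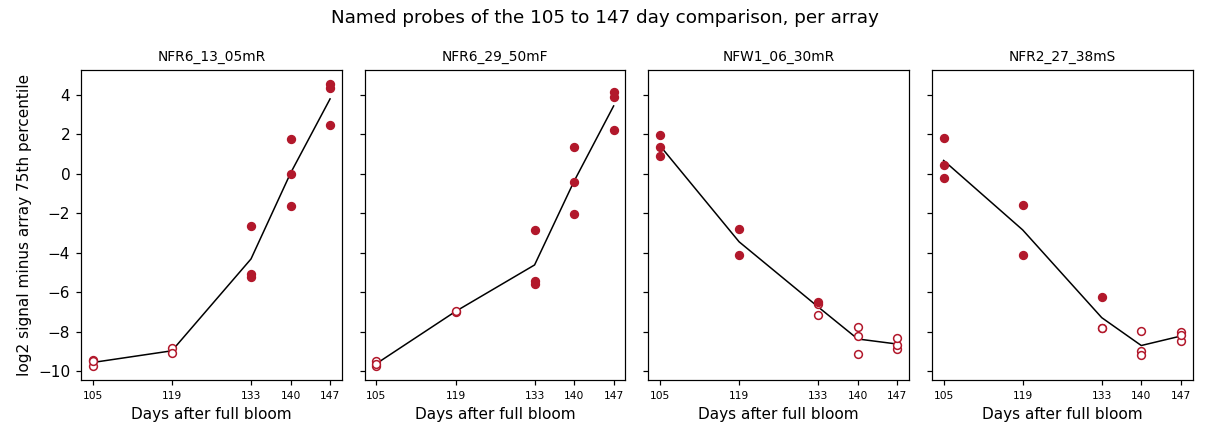
Signal of the 4 named probes of the 105 to 147 day comparison against days after full bloom, as log2 signal minus the array's 75th percentile. Each point is 1 array (filled where the probe was well above background, open where it was not) and the line joins the means; NFR6_13_05mR reached a mean of 3.80 at 147 days, and NFW1_06_30mR started from 1.43 at 105 days.

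Where both probes of a clone were tested, they mostly moved together. Of 6093 such clones, 3108 had both probes past the threshold from 105 to 147 days, of which 1414 rose with both, 1565 fell with both and 129 (4.15%) went opposite ways. With 1 probe per clone, the brightest on average, 680 of 8065 clones rose and 1225 fell at least 2-fold. The balance of rising and falling probes depends on the filter for dim probes and on the scaling. With only probes well above background on all arrays, 4074 rose and 3824 fell, and with no filter 5858 rose and 4960 fell. The probes that changed were 48.25% rising as analysed, 55.22% with quantile normalization and 67.54% with median centring, which shifted the median change by 0.28 on the log2 scale. Of those changed at least 2-fold the rising share was 36.38%, 46.03% and 55.4% in the same order, and with spike-in scaling 1069 rose and 2213 fell. The 147 and 105 day arrays were scanned in different sessions. Within session 1, 4045 probes rose and 4101 fell from 105 to 140 days, and within session 2, 2982 rose and 5051 fell from 119 to 147 days. With slide as a random block the count for 105 to 147 days was 6990.

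The 4 steps of the series divide this change. From 105 to 119 days 3003 probes rose and 1565 fell, of which 793 rose and 489 fell at least 2-fold. NFR6_05_16mR (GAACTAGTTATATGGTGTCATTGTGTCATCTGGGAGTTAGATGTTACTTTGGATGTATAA) rose by 6.88 ± 0.30 (SE) on the log2 scale, from -6.61 ± 0.16 (SD, n = 3) to 0.27 ± 0.75 (SD, n = 2; adjusted p = 5.93e-07), and went on to 5.53 at 147 days. NFR3_22_92mR (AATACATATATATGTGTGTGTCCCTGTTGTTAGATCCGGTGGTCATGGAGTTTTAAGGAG) rose at least 14.29-fold (adjusted p = 0.00504), with an SD of 2.95 between the 2 arrays of 119 days, and this bound was 3.37-fold without array 2 of 119 days and 60.56-fold without array 1. Its mean was back at -7.91 by 133 days. NFR3_27_83mR (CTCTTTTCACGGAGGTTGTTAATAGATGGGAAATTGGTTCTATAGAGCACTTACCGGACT) was at least 16.38-fold lower at 119 days (adjusted p = 4.31e-05) and the F probe of its clone at least 18.12-fold lower (adjusted p = 0.000149). NFW1_06_30mF (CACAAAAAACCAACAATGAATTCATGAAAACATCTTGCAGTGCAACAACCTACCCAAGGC), the F probe of a clone named above, changed by -4.93 ± 0.45 (SE; adjusted p = 3.88e-05) and was well above background on 1 of the 2 arrays of 119 days. This step crosses scan sessions, and both 119-day arrays share 1 slide. With normexp background correction the log2 changes of NFR6_05_16mR, NFR3_22_92mR, NFR3_27_83mR and NFW1_06_30mF were 5.48, 2.76, -2.15 and -2.61. As folds, those of NFR3_22_92mR and NFR3_27_83mR lie below the bounds given. Over the alternatives fixed beforehand the adjusted p of NFR3_22_92mR ranged from 0.000511 to 0.0745, the last with slide as a random block, which left its log2 estimate at 4.51 and counted 1042 rising and 391 falling probes in all. With a block for high spike-in signal, chosen after seeing the data, its adjusted p was 0.165, its estimate 3.29 against 4.51, and 1932 probes rose. The size of that block is set only by array 3 against arrays 1 and 2 of 147 days. Without array 1 of 119 days 1907 rose and 990 fell, without array 2 of 119 days 735 fell, and without array 2 of 105 days 1031 fell. Of the probes changed at least 2-fold, the rising share of 61.86% was 46.02% with quantile normalization, and among all changed probes 65.74% was 55.02%. With spike-in scaling 152 probes rose and 9708 fell in this step.

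From 119 to 133 days 837 probes rose and 2471 fell, and at least 2-fold changes were 134 rising against 1214 falling. NFW3_01_71mF (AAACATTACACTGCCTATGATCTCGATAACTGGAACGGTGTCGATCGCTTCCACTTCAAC) rose at least 6.95-fold (adjusted p = 0.0011) and the R probe of its clone at least 3.06-fold (adjusted p = 0.00592). NFR6_13_05mR, which led the rise to 147 days, rose at least 6.56-fold in this step (adjusted p = 0.00589; 3.69 to 9.04-fold with 1 array left out), while the F probe of its clone was not well above background on any array of either time (adjusted p = 0.833). NFW1_03_53mF (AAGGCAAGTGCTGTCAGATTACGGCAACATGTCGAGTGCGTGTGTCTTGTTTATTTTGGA) changed by -4.97 ± 0.68 (SE; adjusted p = 0.000708; -3.49 with normexp background correction), with 1 of 3 arrays of 133 days well above background, after a mean of 0.67 at 105 days and -2.32 at 119 days. The R probe of its clone, well above background on 1 of 2 arrays at 119 days and on none at 133 days, did not pass the threshold (adjusted p = 0.0848). NFR6_02_03mF changed by -4.93 ± 1.37 (SE; adjusted p = 0.0244), with an SD of 2.79 between the 133-day arrays and a mean back at 2.78 by 140 days. Over the alternatives fixed beforehand its adjusted p ranged from 0.00238 to 0.107, above 0.05 when only the 2 time points were fitted, with slide as a random block and without either array of 119 days or array 2 or 3 of 133 days, where the log2 estimate lay between -5.46 and -4.02. For NFR6_13_05mR the range was 0.00338 to 0.285 and for NFW3_01_71mF 0.000148 to 0.188, both highest with normexp background correction, where the estimates fell from 4.66 to 1.25 and from 4.80 to 1.13. NFR6_13_05mR also missed the threshold with slide as a random block (0.059) and without array 1 of 119 days (0.0528), where its estimates of 4.55 and 4.78 stayed near 4.66. With a block for high spike-in signal, chosen after seeing the data, NFR6_02_03mF changed by -1.36 (adjusted p = 0.635), NFR6_13_05mR by 2.68 (0.214) and NFW3_01_71mF by 2.51 (0.0672). These values rest on 1 array, since only array 3 against arrays 1 and 2 of 147 days sets the size of that block. The excess of falling probes depends on the scaling, since the rising share of 25.3% was 50.63% with quantile normalization and 55.65% with median centring, and 9.94% of at least 2-fold changes became 34.52% with quantile normalization. With spike-in scaling 3089 probes rose and 319 fell in this step. Normexp gave 4535 falling probes, a filter for probes well above background on all arrays left 1316, and slide as a random block left 163 rising and 947 falling. Without array 1 of 119 days 127 rose and 809 fell, without array 2 of 133 days 457 rose and 1644 fell, without array 3 of 133 days 468 rose, and without array 3 of 147 days, which widens the shared spread, 1300 rose.

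From 133 to 140 days, the only step within 1 scan session, 2653 probes rose and 2515 fell, with 380 rising and 436 falling at least 2-fold. DITSSH121F (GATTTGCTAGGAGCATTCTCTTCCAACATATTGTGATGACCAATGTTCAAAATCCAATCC) rose by 5.29 ± 0.85 (SE) on the log2 scale (adjusted p = 0.0016), from -6.72 ± 1.34 (SD, n = 3), with 1 of 3 arrays of 133 days well above background, to -1.43 ± 1.85 (SD, n = 3), or by 3.76 with normexp background correction, and the R probe of its clone rose by 4.57 ± 0.76 (SE; adjusted p = 0.00186). Its mean then reached 1.92 at 147 days. NLE1_11_06mR rose by 5.67 ± 1.06 (SE; adjusted p = 0.00313) from its lowest mean, -5.15, with 2 of 3 arrays of 133 days well above background, but its highest mean was 3.08 at 105 days. NFR6_02_03mF likewise had its lowest mean at 133 days (-1.59) and a higher one at 140 days (2.78). What NFR6_02_03mF and NLE1_11_06mR detect was not tested, so these changes cannot be taken as those of ripening transcripts. NFR2_32_43mR (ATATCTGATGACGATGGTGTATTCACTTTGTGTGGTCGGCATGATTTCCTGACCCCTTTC) changed by -4.20 ± 0.71 (SE; adjusted p = 0.00192; -2.80 with normexp), with 1 of 3 arrays of 140 days well above background, while the F probe of its clone, well above background on 1 of 3 arrays at 133 days and on none at 140 days, was at least 1.62-fold lower (adjusted p = 0.016). This last bound is not firm, since the mean at 133 days includes arrays not well above background. It also hangs on 1 array, since without array 3 of 133 days none can be given. DITDS6_1R (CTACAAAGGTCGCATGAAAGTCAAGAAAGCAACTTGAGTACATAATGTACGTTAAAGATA) was at least 7.92-fold lower at 140 days (adjusted p = 0.00907; 4.12 to 15.4-fold with 1 array left out), and the F probe of its clone changed by -3.34 ± 0.857 (SE; adjusted p = 0.0123). Over the alternatives the log2 change of DITDS6_1R ranged from -5.1 to -2.1. The smallest of these lies, as a fold, below the bound given. With slide as a random block 546 probes rose and 594 fell, and among the alternatives fixed beforehand this was the only one to take the adjusted p of 2 named probes above 0.05, over a range of 0.00187 to 0.0754 for DITDS6_1R and 0.00022 to 0.0503 for NLE1_11_06mR, with log2 estimates of -4.36 against -4.14 and 5.67 as before. Without array 2 of 133 days 1547 rose, and without array 2 of 140 days 1605 fell. The rising share of 51.34% was 35.66% with median centring, and 46.57% of at least 2-fold changes became 31.51%. With spike-in scaling 1086 probes rose and 114 fell in this step.

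From 140 to 147 days, the last week before eating maturity, 2106 probes rose and 2475 fell, with 299 rising and 530 falling at least 2-fold. NFR6_07_07mR (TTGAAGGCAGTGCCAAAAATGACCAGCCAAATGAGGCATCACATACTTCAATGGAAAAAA) rose by 4.68 ± 0.58 (SE) on the log2 scale (adjusted p = 0.000398), after means between -2.51 and -1.27 at the first 4 times, and the F probe of its clone rose by 4.59 ± 0.61 (SE; adjusted p = 0.00054). NFR6_05_44mR (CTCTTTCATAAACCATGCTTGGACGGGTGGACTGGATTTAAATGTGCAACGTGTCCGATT) rose by 5.71 ± 1.26 (SE; adjusted p = 0.00617) with SDs of 2.63 at 140 days, where 2 of 3 arrays were well above background, and 2.48 at 147 days (n = 3 each). NFR4_12_24mR (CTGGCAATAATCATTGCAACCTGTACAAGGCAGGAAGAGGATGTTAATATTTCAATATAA) changed by -3.55 ± 0.46 (SE; adjusted p = 0.000469) and the F probe of its clone, not well above background on any array of 147 days, was at least 9.29-fold lower there (adjusted p = 0.000967). NFR3_11_43mR (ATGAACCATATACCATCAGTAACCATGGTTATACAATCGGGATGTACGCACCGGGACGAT) was at least 4.48-fold lower at 147 days (adjusted p = 0.000304), while the F probe of its clone was not well above background on any array of either time (adjusted p = 0.881). Over the alternatives the log2 change of NFR3_11_43mR ranged from -3.39 to -1.27. The smallest of these lies, as a fold, below the bound given. This step crosses scan sessions. The adjusted p of NFR6_05_44mR ranged from 0.000144 to 0.0796 over the alternatives fixed beforehand and lay above 0.05 with slide as a random block (log2 estimate 5.38) and when only the 2 time points were fitted (5.71). Slide as a random block counted 478 rising and 697 falling probes, and a fit of only the 2 time points 1043 and 1233. Without array 1 of 140 days 1263 rose and 1457 fell, and without array 3 of 140 days 1353 rose and 1649 fell. The rising share of 45.97% was 67.18% with median centring, which left 1506 falling probes, and 36.07% of at least 2-fold changes became 52.79%. With spike-in scaling 132 probes rose and 685 fell in this step.

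**Figure D3:**
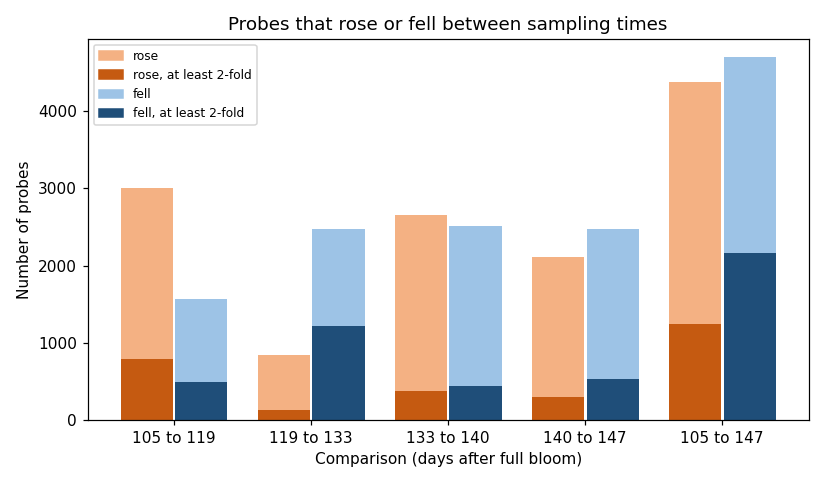
Number of probes (y axis) that rose or fell in each comparison of days after full bloom (x axis), as bars from 0, with the darker part of each bar for changes of at least 2-fold. The 105 to 147 day comparison has the tallest bars, 4383 rising and 4701 falling, and 119 to 133 days has 837 rising against 2471 falling.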

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

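The settings for spike-in scaling, the block for high spike-in signal, the trend with scan session and the contrasts within a session were chosen after seeing the data, and the other settings before. The named probes kept their direction under every setting that gave them a value: of 544 such values, 522 were on the same side of the threshold or within 1 SD, 19 missed the threshold, and 3 from the authors' table, which has no test, lay over 1 SD away (11.77 for NFR6_13_05mR and 11.41 for NFR6_29_50mF from 105 to 147 days, 3.63 for NFW3_01_71mF from 119 to 133 days). Normexp moved these estimates further, to 9.60, 9.32 and 1.13, which as folds lie below the lower bounds given above. Where a change ended or moved a count, the cause was not tested unless stated. Signal near background limits the folds that can be measured, which are then lower bounds for the background correction of the main fit.

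The count of probes that differ between the 5 times was 11981, between 11285 and 12818 with an array left out, 8646 with slide as a random block, and 7113 as a linear trend in days, which asks for steady change only. With scan session added to the trend it was 7334, of which 6685 were also called, with the same direction, without it. In that fit the session term passed the threshold for 1095 probes, and it can also hold change that is not linear in days. Asking for at least 2-fold changes left, by construction, 1282 probes from 105 to 119 days (793 rose, 489 fell), 1348 from 119 to 133 days (134 and 1214), 816 from 133 to 140 days (380 and 436), 829 from 140 to 147 days (299 and 530) and 3406 from 105 to 147 days (1239 and 2167). The authors' deposited table, with no test, had 3459 probes at least 2-fold apart from 105 to 147 days, 891 higher and 2568 lower.

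With slide as a random block the counts in the same order were 1433 (1042 rose, 391 fell), 1110 (163 and 947), 1140 (546 and 594), 1175 (478 and 697) and 6990, and 900 probes were highest at 140 days. The correlation within slides was estimated at 0.401, and at -0.285 without array 3 of 147 days, which is alone on its slide, so that array sets the estimate. Only 133 and 147 days span 2 slides. Whether the array numbers pair arrays of different times stays open. Deviations of the 26 same-numbered pairs of arrays correlated across probes between -0.239 and 0.377 (median 0.057), with 11 above 0.1, against 10 of 52 differently numbered pairs (median -0.021), and for 133 and 147 days all 3 same-numbered pairs were above 0.1 (0.237, 0.148 and 0.228). A replicate block gave 4978, 3429, 5526, 4773 and 9234 probes in the same order and 12213 for the F-test. It moved no count by over 1.5 times.

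With each array left out in turn, the 105 to 119 day count ranged from 2756 to 5955 (rose 1907 to 3741, fell 735 to 2214), 119 to 133 days from 936 to 4510 (rose 127 to 1300, fell 809 to 3210), 133 to 140 days from 3235 to 6768 (rose 1547 to 3452, fell 1605 to 3316), 140 to 147 days from 2720 to 5143 (rose 1263 to 2290, fell 1457 to 2853) and 105 to 147 days from 8185 to 9699 (rose 3885 to 4758, fell 4300 to 4941). The highest value of each of these came without array 3 of 147 days. Where 1 array of 119 days was left out, the other was assumed to vary like the other groups. Probes highest at 105 days numbered 2922 to 3297, at 119 days 2497 to 3289, at 133 days 1135 to 1452, at 140 days 1394 to 1929 and at 147 days 2690 to 3502.

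From 119 to 133 days 1495 rose and 1458 fell with quantile normalization, which shifted the median change by 0.11 on the log2 scale, and 1986 and 1583 with median centring, which shifted it by 0.20. Median centring shifted the other steps by 0.07, -0.12 and 0.14 in time order, left 1506 falling probes from 140 to 147 days, and put 2522 probes highest at 133 days. Normexp gave 5400 changed probes from 119 to 133 days, 4535 of them falling. A filter for probes well above background on all arrays gave 2067 there, 1316 falling, and no filter put 2142 highest at 133 days. A fit of only 140 and 147 days gave 2276 (1043 rose, 1233 fell), with fewer arrays for the spread. With spike-in scaling the median changes were -1.16, 0.91, 0.49 and -0.34 for the 4 steps and -0.06 from 105 to 147 days, against 0.07, -0.09, 0.00 and -0.03 and -0.01 as analysed. It gave 9860 probes from 105 to 119 days (152 rose, 9708 fell), 3089 rising and 319 falling from 119 to 133 days, 1200 from 133 to 140 days (1086 and 114), 817 from 140 to 147 days (132 and 685) and 3282 from 105 to 147 days (1069 and 2213), with 169 probes highest at 119 days, 190 at 133, 5894 at 140 and 1624 at 147 days. Its array-wide error is shared by all probes (prior degrees of freedom 232.4 against 2.40), so its p-values assume an independence that does not hold. A block for high spike-in signal, its size set only within 147 days by array 3, left 1932 rising probes from 105 to 119 days.

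The direction balance from 105 to 147 days depended on the filter for dim probes and on the scaling. Among all changed probes, 4383 rose and 4701 fell as analysed. With only probes well above background on all arrays the counts were 4074 and 3824, and with no filter 5858 and 4960. Of probes changed at least 2-fold, 63.6% fell as analysed, 54% with quantile normalization, 44.6% with median centring and 67.4% with spike-in scaling, so whether more probes fell than rose cannot be told apart from the scaling of the arrays. The set tests of the 30 gene lists, with their alternatives of an estimated correlation and of all probes in the lists, were not run, because no gene description was used here.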

Other observations

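Tests that were chosen only after their result was seen are those of scan session on arrays that did not choose the probes, of the other probe of a clone, of a mislabelled array, of the scaling of the arrays, of the clone prefixes starting with DIT, and the splits of the 105 to 140 day arrays. Clone names carry prefixes whose meaning the files do not state. Taking the brightest probe of each clone, 74 of the 305 tested clones with prefixes starting with DIT changed at least 2-fold from 105 to 147 days, and 55 of them rose (74.3%, 95% exact interval 62.8% to 83.8%). Of 1831 such clones with other prefixes, 625 rose (34.1%, 95% exact interval 32.0% to 36.4%; two-sided Fisher's exact p = 8.46e-12). By prefix, the counts were 22 rising and 1 falling in DITSSH, 15 and 1 in DIT, 5 and 0 in DITK, and 13 and 17 in DITNO. The contrast between the 2 kinds held under each scaling, at 75.9% against 41.3% with quantile normalization, 85.1% against 52.6% with median centring, 75% against 34.6% with normexp and 70.7% against 30.1% with spike-in scaling. Several clones can come from 1 transcript, so clones are not independent and this p is too small. For clones of the prefix NLE, the share that fell was 5.79 percentage points above that of all others (two-sided Fisher's exact p = 0.0595), which leaves a difference open.

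Probes of the prefix DITNO peaked at 119 days more often than other probes. Of 149 DITNO probes tested, 48 (32.2%, from 45 clones) were highest at 119 days and at least 2-fold above 105 and 133 days, against 459 of 14009 other probes (3.28%; two-sided Fisher's exact p = 5.21e-33, with the same limit). The median rise of these 48 probes at 119 days was 2.33 on the log2 scale, against 1.79 for the others. They stood higher on array 3 of 147 days than on arrays 1 and 2 by a median of 1.20, against 0.703 for the others. That array shares the high spike-in signal of the 119-day arrays, so a shared labelling batch stays a candidate explanation for this peak.

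Changes across scan sessions were weighed first: probes at least 2-fold apart between 1 array of 105 days and 1 of 147 days were tested on the other arrays, for each of the 9 choices of that pair, where a change due to session alone would be near 0 within a session. In the direction of the choice, the median log2 change was 1.03 to 1.21 from 105 to 140 days and 1.13 to 1.27 from 119 to 147 days, each within a session, against 1.43 to 1.73 from 105 to 147 days, so the smaller was 0.677 to 0.759 of the whole, which argues against scan session alone as the source of these changes. The changes from 105 to 140 days and from 119 to 147 days share no array and correlated across probes with r = 0.77, with 2002 probes rising in both against 852 for independent lists, 2893 falling in both against 1460, and 516 called in opposite directions. RNA loss at 1 end of transcripts would part the 2 probes of a clone whichever end each lies near. Of the clones with both probes called, 4.15% went opposite ways, and of 1064 with both changed at least 2-fold 12 did. The median change of F minus R was 0.03 on the log2 scale from 105 to 147 days, and -0.10 to 0.13 over the steps. These shares leave out clones with 1 probe called, and the median would cancel if F lay near different ends in different clones. Over all 6093 clones with both probes tested, the 2 changes from 105 to 147 days correlated with r = 0.852. This correlation argues against loss at 1 end as the only source of the changes from 105 to 147 days. For probes changed at least 2-fold (median 1.68), the other probe of the clone changed by a median of 1.54 the same way (2833 probes). Clones with both probes changed at least 2-fold enter with each of them, so the 2 medians are alike in part by construction. Slide stays open, because each slide held 1 time point, and so does RNA loss that lowers whole transcripts, while the files do not give the distance between F and R.

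Array 3 of 147 days and the peak at 119 days were weighed together. That array lies at least 2-fold from the mean of arrays 1 and 2 for 1105 probes, against 192 between arrays 1 and 2, and its spike-in signal of 1.90 above the 75th percentile is near that of the 119-day arrays (2.06 and 2.18), with 0.67 and 0.24 on its fellows. Its mean correlation was 0.9842 with the other 147-day arrays and 0.9178, 0.9487 and 0.9685 with 105, 119 and 133 days. This argues against a mislabelled array of those 3 times. For 140 days, with a mean of 0.9791, the test cannot decide. Array 3 correlated at 0.9834 with array 2 of 140 days and at 0.9839 and 0.9846 with its fellows. Its deviation correlated across probes at 0.372 with that of the 119-day arrays from 105 and 133 days, and at -0.383 with the change from 105 to 140 days, so a shared labelling batch and fruit at an earlier stage of ripening are both candidate explanations, together accounting for 27.9% of its variance. Over the 507 probes that peaked at 119 days, array 3 stood above arrays 1 and 2 by 0.408 of that peak (86.4% of them higher, against 53% of all probes). Arrays 1 and 2 of 147 days stood above 140 days by 0.139 of it. This cannot decide on scan session, since that difference also holds the change from 140 to 147 days. The 507 probes were also chosen as highest at 119 days, which leaves out probes higher at 147 days. Part of the 119-day peak may be technical, and this cannot be told apart from biology with 2 arrays on 1 slide.

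More probes fell than rose by at least 2-fold from 105 to 147 days, and this was weighed against scaling. The falling share ranged from 44.6% to 67.4% over quantile, median and spike-in scaling, so it stays open. In the authors' table, with no test, 891 probes were at least 2-fold higher and 2568 lower. Falls were more frequent among dim probes, with 949 falling against 326 rising in the dimmest of 4 equal classes by mean signal and 247 against 311 in the brightest. From dimmest to brightest, the median log2 change was -0.225, -0.0783, 0.0419 and 0.13. A dim probe could enter through 105 days alone, where 13559 probes were well above background on all arrays, against 12417 at 147 days. This excess of falls therefore cannot be told apart from the filter. Changes of transcript amount per fruit cell were not tested.

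Other groupings of the arrays gave fewer probes. For the F-test 1 of 100 splits of the 14 arrays, the real one, reached 11981 probes, and the highest of the others gave 3856. This argues against a random grouping of arrays as the source of the count. Each slide held 1 time point, so the real grouping splits no slide, and the test cannot part time from slide. For 105 to 147 days, 1 of 10 splits of the 6 arrays, the real one, gave 9084, and the highest of the others gave 0; for 133 to 140 days the values were 1 of 10, 5168 and 0, for 140 to 147 days 1 of 10, 4581 and 197, and for 105 to 140 days 1 of 10, 8146 and 0. With 10 splits no share under 0.05 is possible.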
